A study of Tachysurus vachellii and Tachysurus fulvidraco x Tachysurus vachelli and Tachysurus fulvidraco with 9 samples.

How the data were processed

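Poly(A) RNA from the liver of juvenile P. vachelli, P. fulvidraco and their hybrid was sequenced in 9 libraries, 3 per line, per the labels. The deposited values are TPM per assembled gene and library, computed by the authors before deposit, and each library sums to 1000000 TPM or within a few units of it. Per the submitters' processing notes, reads were handled with cutadapt, which trims adapters, and FastQC, which reports read quality, with no version given. The row identifiers are those of a Trinity assembly, per the file headers and the identifiers themselves. The aligner or quantifier, the settings of the assembly and the source of the gene names are not given in the sources used here. One label speaks of adipose type in the extraction protocol while the tissue is given as liver, and the tissue label was followed. Columns were matched to samples by the library titles, and 0 columns of values stayed without a sample.

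The table held 57710 rows, of which 23166 had a protein description and 17769 a gene symbol. These made 11137 different symbols, and 7041 of them were also in the RefSeq gene table of P. vachelli, which was used for nothing else. Symbols and descriptions were taken from the deposited table, and where they disagree the text gives the description. No genome was used, so no coordinates are given. A gene can have several rows, and 3335 symbols had more than 1 tested row. Close relatives in a gene family may share reads, and how the quantification split them is unknown. TPM keep no depth, the depth of the libraries is unknown, and no counting interval or floor is given. The highest Pearson correlation across genes between libraries of a group was 0.937, and no pair was alike enough to be 1 library deposited again.

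Rows with at least 1 TPM in at least 3 of the 9 libraries were tested, 51225 in all. The test was limma with an intensity trend (limma 3.58.1, R 4.3.3) on log2(TPM + 1), in 1 fit of all 9 libraries with a group factor and 6 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment at 0.05. The comparisons were the hybrid against each parent, the parents against each other, and the hybrid against the mean of the parental coefficients. A row was outside the parental range where the hybrid differed from both parents in the same direction. For the mid-parent on the linear scale, the mean log2(TPM + 1) of each parent was taken back to the linear scale. The log2 of the mean of both parents was then used. Its test took the standard error of the log-scale comparison. Gene lists were tested with camera of limma at its preset correlation of 0.01, Benjamini-Hochberg adjusted over the 37 lists within a comparison. No list call held with the correlation estimated per list, where camera called 0 lists and 1 of the tests had an unadjusted p under 0.05. List symbols were matched without regard to case and with the suffixes that mark fish duplicates, and the row of highest mean TPM stood for a symbol. Function lists needed 5 and marker lists 3 measured members. Of 39 lists, those of egg yolk proteins and of kidney had 2 measured members each and were not tested.

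The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The design allowed for counts or for normalized values, and the table held TPM, so the test set for normalized values was used. Named genes were, in each comparison, the 8 largest rises and 8 largest falls among called rows that had a name, at least the median mean level and no overlap between groups, the 8 rows farthest above and the 8 farthest below both parents, and in each list up to 4 members with the smallest p. Any list gene could be named to give its value. Genes were preferred where the calls held in the alternatives, and some genes that the rule names are not reported here. The rows named in a single parent, the mitochondrial rows and the vitellogenin rows were chosen after their values were seen.

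The alternatives were quantile normalization, median-ratio scaling, no trend, no filter or a filter of 5 TPM, pseudocounts of 0.1 and 5, a minimum absolute log2 difference of 1, a fit of only the compared groups, the replicate number as a block, leaving out each library, a linear mid-parent, and for lists an estimated correlation and every row of a symbol. Chosen after seeing the data were the sum of the rows of a symbol, rows with both parents at 1 TPM or more, rows with a protein description, a delta-method error for the linear mid-parent, and a fit without P. fulvidraco 1 and 2.

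The test was tested on simulated data made from 51225 genes in each comparison. Only a small part of these genes was changed, so the adjusted cut-off was stricter than in the data. The changed genes counted here and the additive genes were drawn from those above the median mean level. Genes of low level are thus not covered. The shares called need not apply to the real comparisons. It called 25% of genes changed by 1 and 71% of genes changed by 2 on the log2 scale for the hybrid against P. vachelli, 26% and 72% against P. fulvidraco, and 37% and 76% against the mid-parent. Of its calls, 7.41%, 6.36% and 6.92% were on unchanged genes. Against the mid-parent, 54.8% of additive genes with a 16-fold parental difference were called on the log scale and 0% on the linear scale, so that the log-scale mid-parent calls additive genes whose parents differ widely.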

Results

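Transcript levels were measured by paired-end sequencing of poly(A) RNA from the liver of juvenile catfish. The 9 libraries fell into 3 groups of 3: the darkbarbel catfish Pelteobagrus vachelli, the yellow catfish P. fulvidraco, and the hybrid Huangyou-1 from P. fulvidraco mothers and P. vachelli fathers. Each line was reared in its own aquaria, so line and rearing go together in every comparison. The labels do not say whether a library came from 1 fish or a pool, and p-values then measure only the spread between these samples, which may be technical. The deposited table held 57710 assembled genes, here called rows, with values in TPM. TPM keep no read depth, so the depth of the libraries is unknown. Between 36107 and 41016 rows reached 1 TPM in a library, and the 10 most abundant rows took 20.2% to 25.2% of the TPM. In what follows, ± after a TPM level is the SD over n = 3 libraries and ± after a log2 difference is its standard error from limma, on the log2(TPM + 1) scale. That scale understates the change of genes with low values.

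Mitochondrial transcripts, which are inherited from the mother, checked the labels of the hybrid. The P. fulvidraco form of mt-co2, cytochrome c oxidase subunit II, stood at 12283 ± 217 TPM in the hybrid and 12211 ± 868 TPM in P. fulvidraco, against 0.223 ± 0.387 TPM in P. vachelli. The P. vachelli form stood at 21480.3 ± 1296 TPM in P. vachelli and at 1.28 ± 1.27 TPM in the hybrid. The ATP synthase gene mt-atp6 divided in the same way, with 3937 ± 89.7 TPM of the P. fulvidraco form in the hybrid and 6631 ± 236 TPM of the other form in P. vachelli. The P. fulvidraco forms of mt-cyb, cytochrome b, and MT-ND2, a subunit of complex I, stood at 1980.3 ± 57.7 and 1028 ± 41.8 TPM in the hybrid, against 1731 ± 55.6 and 1366 ± 68.1 TPM in P. fulvidraco. The row of MT-ND3 was listed at 0 in all hybrid and P. fulvidraco libraries and stood at 1603 ± 36.9 TPM in P. vachelli. All 3 hybrid libraries thus carried the maternal transcripts that their labels call for. The list of mitochondrially encoded respiratory genes had 5 of 11 measured members higher and 5 lower (5 and 5 adjusted over the list alone) in P. vachelli against P. fulvidraco. It was not called (camera adjusted p = 0.591), and its median, mean and test differed in sign (median log2 difference 0.32, mean -3.09 and camera direction down). For mt-co2, mt-atp6, mt-cyb and MT-ND2 the row that stood for the symbol was the P. fulvidraco form, near 0 TPM in P. vachelli. These members were thus lower through the choice of row, although P. vachelli had its own form of each. With the rows of a symbol summed, an alternative chosen after seeing the data, the list was called higher in P. vachelli, with 10 of 11 members higher and 1 lower (camera adjusted p = 0.000788, in a range of 0.000788 to 0.838 over the alternatives with the preset correlation). Summed in this way it was also called lower in the hybrid than in P. vachelli, with 0 higher and 10 lower (camera adjusted p = 4.84e-07, range 4.84e-07 to 0.646), and lower than the mid-parent, with 0 and 9 (camera adjusted p = 8.08e-09, range 8.08e-09 to 0.924). All 3 calls were lost with an estimated correlation on the summed rows (adjusted p = 0.815 between the parents, 0.217 for the hybrid against P. vachelli and 0.126 against the mid-parent). Since the hybrid held the maternal forms, a level like that of P. fulvidraco already places it below P. vachelli and the mid-parent. Both hybrid calls are thus no separate evidence of a change in the hybrid. Against P. fulvidraco the list was called in 0 of the 15 alternatives with the preset correlation (camera adjusted p = 0.155 to 0.661). For MT-ND3 the sum changes little, as its row was found in P. vachelli only.

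**Figure D1:**
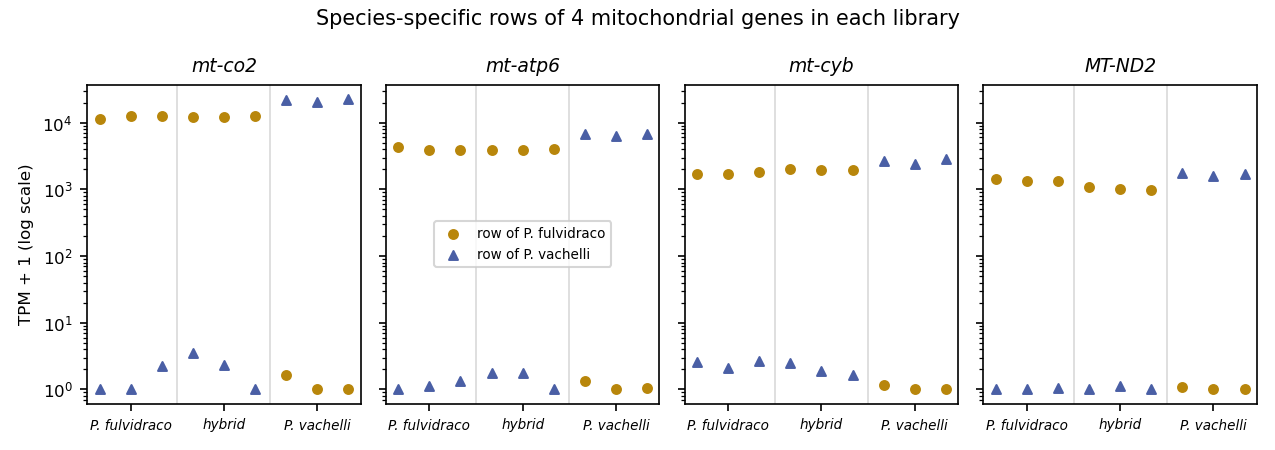
Levels in TPM of species-specific mitochondrial rows in the 9 libraries. The hybrid libraries hold the P. fulvidraco forms, with mt-co2 at 12283 ± 217 TPM (mean ± SD, n = 3), and are near 0 in the P. vachelli forms.

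Over the tested rows, libraries of the parents were less alike than libraries of the hybrid and either parent. Spearman's rho over the tested rows, a value across genes, which are not independent replicates, was 0.216 to 0.245 between the parents. It was 0.559 to 0.610 between the hybrid and P. fulvidraco, and 0.495 to 0.524 between the hybrid and P. vachelli. The tested rows include 1454 found in P. fulvidraco but not P. vachelli and 1349 found the other way round, as defined below. Rows that hold the form of a single species lower rho between the parents, while a hybrid with both forms shares rows with each. The order of these values is therefore no measure of how far liver expression differs. Within the groups it was 0.683 to 0.727 in the hybrid, 0.805 to 0.866 in P. fulvidraco and 0.856 to 0.872 in P. vachelli. The first principal component held 62.3% of the variance. On the third, with 6.63%, hybrid 3 stood apart at 114 from hybrid 1 and 2 at -48.1 and -42.5, and P. fulvidraco 3 at -45.5 from P. fulvidraco 1 and 2 at 19.3 and 12.8.

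The first comparison set P. vachelli against P. fulvidraco, to describe the difference between the lines that were crossed. Here and below, the level of a named gene is that of a single row unless a sum is stated. A row can hold the form of a single species, as with mt-co2, so its difference need not be that of the whole gene. Of the interferon-induced genes, IFI44 stood at 236 ± 67.9 TPM in P. vachelli against 2.86 ± 1.35 TPM in P. fulvidraco (log2 difference 5.95 ± 0.29) and its relative IFI44L at 26.6 ± 3.27 against 0.747 ± 0.179 TPM (3.98 ± 0.14). The scavenger receptor CD163 went the other way, with 4.73 ± 1.46 TPM in P. vachelli and 836 ± 63.2 TPM in P. fulvidraco (-7.22 ± 0.22). Nuclear genes of oxidative phosphorylation were lower in P. vachelli by the list test, with 44 of 66 members lower (camera adjusted p = 2.7e-05, and adjusted p = 0.997 with an estimated correlation). They were led by NDUFA2, a subunit of complex I, at 19.3 ± 1.21 against 181 ± 11.4 TPM (-3.17 ± 0.08).

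That list of oxidative phosphorylation genes was the only 1 of 37 called between the parents, with 8 higher and 44 lower of 66 measured members, 9 and 45 adjusted over the list alone (median log2 difference -0.46). Besides NDUFA2, the ATP synthase subunits ATP5J2 and ATP5I fell to 114 ± 8.78 and 97.9 ± 6.89 TPM from 395 ± 33.3 and 259.6 ± 14.1 TPM (log2 differences -1.78 ± 0.09 and -1.40 ± 0.10). The cytochrome c oxidase subunit Cox8a was higher, at 479.5 ± 30.8 against 304 ± 17.7 TPM (0.65 ± 0.08).

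The following lists were not called between the parents, although many members were. The interferon response list had 11 higher and 7 lower of 27 measured members, 11 and 7 adjusted over the list alone. The antiviral nuclease gene samhd1 was listed at 0 in P. fulvidraco and stood at 6.17 ± 1.62 TPM in P. vachelli. The antioxidant list had 9 higher and 4 lower of 27 measured members, 9 and 4 adjusted over the list alone. The superoxide dismutase sod1 rose from 113 ± 20.7 to 654 ± 33.0 TPM (2.53 ± 0.14) and the peroxiredoxins PRDX5 and PRDX6 by 1.77 ± 0.11 and 1.65 ± 0.09 on the log2 scale, while the lipid peroxidase GPX4 went from 1228 ± 149.8 to 625 ± 39.1 TPM (-0.97 ± 0.11). The xenobiotic metabolism list had 8 higher and 14 lower of 30 measured members, 8 and 14 adjusted over the list alone. The cytochrome P450 gene cyp3a40 stood at 531 ± 49.4 TPM in P. fulvidraco and 47.2 ± 6.85 TPM in P. vachelli (-3.47 ± 0.15), aldehyde oxidase AOX1 at 360.4 ± 13.3 and 37.5 ± 6.94 TPM (-3.24 ± 0.13), and the glutathione transferase GSTM3 at 14.2 ± 2.52 and 206 ± 12.2 TPM (3.78 ± 0.14).

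Genes of amino acid breakdown showed 14 higher and 22 lower of 49 measured members, 14 and 22 adjusted over the list alone. Arginase ARG1, the last step of the urea cycle, was at 347 ± 103 TPM in P. fulvidraco and 25.4 ± 3.07 TPM in P. vachelli (-3.68 ± 0.21), the alanine aminotransferase Gpt2 at 50.3 ± 2.56 and 0.170 ± 0.176 TPM (-5.46 ± 0.13), and proline dehydrogenase PRODH at 25.3 ± 3.42 and 1.5 ± 0.280 TPM (-3.39 ± 0.24). Fatty acid oxidation had 13 higher and 7 lower of 28 measured members, 13 and 7 adjusted over the list alone. The medium-chain acyl-CoA dehydrogenase ACADM fell from 184 ± 5.5 to 71.5 ± 5.84 TPM (-1.36 ± 0.08). Among plasma proteins, the complement list had 12 higher and 5 lower of 24 measured members, 12 and 5 adjusted over the list alone, and the coagulation list 4 higher and 13 lower of 25 measured members, 4 and 13 adjusted over the list alone. The pore-forming C9 was higher in P. vachelli at 4767 ± 299 against 539 ± 32.1 TPM (3.14 ± 0.10), as was heparin cofactor SERPIND1 at 3176 ± 184 against 775 ± 16.4 TPM (2.03 ± 0.09), and coagulation factor F5 was lower at 139 ± 3.29 against 279.9 ± 14.7 TPM (-1.0 ± 0.08). The hepatocyte markers showed 6 higher and 9 lower of 18 measured members, 6 and 9 adjusted over the list alone, among them antithrombin Serpinc1 at 1276 ± 43.9 against 2124 ± 129.7 TPM (-0.73 ± 0.09). Endothelial markers had 6 higher and 2 lower of 12 measured members, 6 and 2 adjusted over the list alone, with the transcription factor FLI1 at 7.99 ± 0.201 against 3.95 ± 0.459 TPM (0.86 ± 0.15). Intestinal markers had 3 higher and 1 lower of 5 measured members, 3 and 1 adjusted over the list alone, and the microRNA pathway 3 higher and 3 lower of 12 measured members, 3 and 3 adjusted over the list alone (median log2 difference -0.25, mean 0.10 and camera direction down). The helicase gene mov10b.1 led the latter, at 38.8 ± 2.04 against 3.01 ± 0.205 TPM (3.31 ± 0.13).

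Egg yolk proteins were abundant in part of the P. fulvidraco libraries. The 4 vitellogenin rows together held 5.08% of the TPM in P. fulvidraco 1, 1.88% in P. fulvidraco 2 and 0.00549% in P. fulvidraco 3, and at most 0.000129% in any other library. Another row, described as vitellogenin fused with superoxide dismutase, was left out of that sum: it was listed at 0 in all P. fulvidraco libraries and stood at 2.19, 6.98 and 6.69 TPM in hybrid 1, 2 and 3. The estrogen receptor esr1, which drives vitellogenin synthesis in fish liver, was at 32.2, 30.4 and 1.98 TPM in P. fulvidraco 1, 2 and 3. Only 2 members of the egg yolk list and 2 of the kidney list were measured, too few for the list test. The kidney members slc20a1b and SLC34A2, phosphate transporters, stood at 13.4 ± 3.88 and 2.37 ± 4.11 TPM in P. fulvidraco and at 2.21 ± 0.452 and 1.36 ± 0.809 TPM in P. vachelli.

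Over all tested rows, limma called 14058 rows higher and 13797 lower in P. vachelli, 54.4% of 51225. After summing the rows of a symbol, an alternative chosen after seeing the data, 2585 of 10815 symbols were higher and 2666 lower. Without P. fulvidraco 1 and 2, the libraries rich in vitellogenin (also chosen after seeing the data), 16960 rows were called in either direction.

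The second comparison asked how the hybrid differed from its paternal species, P. vachelli. Nuclear genes of oxidative phosphorylation were higher in the hybrid by the list test, with 30 of 66 members higher and 33 not called (adjusted p = 0.774 with an estimated correlation). NDUFA2 stood at 106 ± 4.94 TPM against 19.3 ± 1.21 TPM in P. vachelli (log2 difference 2.40 ± 0.08) and ATP5J2 at 255 ± 9.32 against 114 ± 8.78 TPM (1.15 ± 0.09). Of the chaperones of the endoplasmic reticulum, 15 of 28 were lower (adjusted p = 0.774 for the list with an estimated correlation), such as the protein disulfide isomerase P4HB at 115 ± 7.85 against 206 ± 10.8 TPM (-0.83 ± 0.11) and the secreted stress protein MANF at 6.49 ± 0.656 against 29.3 ± 3.44 TPM (-2.01 ± 0.24). Interferon response genes went both ways, with 5 higher and 7 lower of 27 measured members, 6 and 9 adjusted over the list alone, and the list was not called (camera adjusted p = 0.396). IFI44 fell to 7.27 ± 1.52 from 236 ± 67.9 TPM (-4.81 ± 0.29), while the antiviral GTPase gene mx was higher at 4.71 ± 0.727 against 0.147 ± 0.106 TPM (2.31 ± 0.33).

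Of 37 lists, 5 were called against P. vachelli. The list of oxidative phosphorylation genes had 30 higher and 3 lower of 66 measured members, 32 and 3 adjusted over the list alone (median log2 difference 0.28, camera adjusted p = 5.23e-05, and adjusted p = 0.774 with an estimated correlation). Further members above P. vachelli were ATP5I at 214 ± 21.5 TPM (1.12 ± 0.10) and ndufa4 at 569.7 ± 25.7 TPM (0.52 ± 0.07). The endoplasmic reticulum list had 2 higher and 15 lower of 28 measured members, 3 and 16 adjusted over the list alone (median -0.62, camera adjusted p = 0.00208, and adjusted p = 0.774 with an estimated correlation). Its abundant members HSPA5, the chaperone BiP, and HSP90B1 stood at 28.6 ± 6.46 and 38.1 ± 1.18 TPM in the hybrid and at 70.2 ± 24.6 and 119 ± 28.4 TPM in P. vachelli, and HSP90B1 differed by -1.59 ± 0.26. The disulfide isomerase Pdia6 differed by -1.51 ± 0.20 and the co-chaperone Dnajb11 by -1.21 ± 0.16.

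Cytosolic ribosomal proteins had 24 higher and 7 lower of 78 measured members, 24 and 7 adjusted over the list alone (median 0.16, camera adjusted p = 0.0112, and adjusted p = 0.774 with an estimated correlation). Rplp2 was at 688 ± 105 against 48.4 ± 6.81 TPM (3.80 ± 0.13) and RPS15A at 1121 ± 79.3 against 221 ± 33.3 TPM (2.35 ± 0.12), while RPS12 was lower at 735 ± 3.20 against 1039.9 ± 26.4 TPM (-0.50 ± 0.09). Markers of pancreatic acinar cells, which in many bony fishes lie within the liver, had 8 higher and 1 lower of 12 measured members, 10 and 1 adjusted over the list alone (median 1.31, camera adjusted p = 0.0114, and adjusted p = 0.774 with an estimated correlation). Elastase CELA2A stood at 2127 ± 338 TPM in the hybrid and 481 ± 211 TPM in P. vachelli (2.22 ± 0.40), Cela3b at 16.7 ± 3.13 and 4.78 ± 1.81 TPM (1.65 ± 0.28), and trypsin Try3 at 1039.8 ± 189 and 328 ± 119.7 TPM (1.70 ± 0.34). The member that was lower, with the symbol Prss2, carries a description as a complement C1s subcomponent, which is a plasma protein and no acinar product (299 ± 86.2 against 519 ± 67.7 TPM, -0.82 ± 0.19). The acinar call was lost without hybrid 1 (camera adjusted p = 0.0876) and without P. vachelli 3 (0.0508), in a range of 0.000786 to 0.0876 over the alternatives with the preset correlation, and the ribosomal call without hybrid 1 (camera adjusted p = 0.0876) and without P. vachelli 3 (0.0508), in a range of 2.88e-05 to 0.0876 over the alternatives with the preset correlation. Erythrocyte markers had 4 higher and 0 lower of 10 measured members, 4 and 0 adjusted over the list alone (median 0.48, camera adjusted p = 0.0494, and adjusted p = 0.774 with an estimated correlation). The heme synthesis gene alas2 was at 20.2 ± 3.83 against 11.4 ± 1.82 TPM (0.77 ± 0.16), while hemoglobin hba was at 5810.0 ± 882 and 5439 ± 1126 TPM and was not called. This list's call was lost under median-ratio scaling (camera adjusted p = 0.0561), with every row of a symbol as a member (0.205), without hybrid 1 (0.183), without P. vachelli 2 (0.110) and without P. vachelli 3 (0.175), in a range of 0.00811 to 0.205 over the alternatives with the preset correlation.

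Other lists were not called against P. vachelli as a whole. Lipoprotein genes had 7 higher and 4 lower of 17 measured members, 8 and 4 adjusted over the list alone, with cholesteryl ester transfer protein CETP at 117 ± 5.07 against 260.0 ± 32.1 TPM (-1.14 ± 0.10) and hepatic lipase LIPC at 37.3 ± 5.66 against 114 ± 6.73 TPM (-1.59 ± 0.21). The acute phase and iron list had 4 higher and 7 lower of 19 measured members, 4 and 7 adjusted over the list alone (median log2 difference 0.03, mean 0.06 and camera direction down). Its member hpx, described as the heme-binding warm temperature acclimation protein, was among the most abundant liver transcripts, at 23062 ± 2285 TPM in the hybrid against 2300.1 ± 679 TPM (3.36 ± 0.25), and transferrin tf stood at 10849.9 ± 1251 against 5515 ± 559 TPM (0.97 ± 0.15). The circadian list had 6 higher and 1 lower of 22 measured members, 6 and 1 adjusted over the list alone. The PAR bZIP factor TEF was at 11.6 ± 1.0 against 6.03 ± 0.522 TPM (0.84 ± 0.11) and the clock output repressor nfil3 at 53.1 ± 7.88 against 8.82 ± 4.18 TPM (2.53 ± 0.28). Biliary markers had 1 higher and 4 lower of 10 measured members, 1 and 4 adjusted over the list alone, with annexin ANXA4 at 182 ± 15.7 against 114 ± 7.46 TPM (0.66 ± 0.09). Neutrophil markers had 0 higher and 2 lower of 7 measured members, 0 and 2 adjusted over the list alone (median log2 difference 0.19, mean -0.15 and camera direction down), and the collagenase MMP13 was at 17.2 ± 3.04 against 37.7 ± 1.63 TPM (-1.10 ± 0.14) and the oxidase subunit Ncf1 at 13.6 ± 1.99 against 25.3 ± 0.602 TPM (-0.86 ± 0.14). Islet markers had 1 higher and 0 lower of 4 measured members, 2 and 0 adjusted over the list alone, and insulin ins varied between the hybrid libraries (63.1 ± 72.3 TPM).

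Over all tested rows, 7928 were called higher and 7460 lower in the hybrid (limma, 30.0% of the rows). Summed per symbol, 1477 symbols were higher and 1825 lower, and under quantile normalization 6312 rows were higher and 8381 lower. The count depended on the P. vachelli libraries, falling to 9320, 9480 and 9043 without P. vachelli 1, 2 or 3.

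The third comparison set the hybrid against its maternal species, P. fulvidraco. Of the endoplasmic reticulum chaperones, 18 of 28 were lower in the hybrid here (adjusted p = 0.931 for the list with an estimated correlation). HSPA5 stood at 28.6 ± 6.46 TPM against 131 ± 55.9 TPM in P. fulvidraco (log2 difference -2.08 ± 0.36), P4HB at 115 ± 7.85 against 188 ± 24.3 TPM (-0.69 ± 0.11) and MANF at 6.49 ± 0.656 against 19.0 ± 6.72 TPM (-1.36 ± 0.24). Of the translation factors, 17 of 38 were lower and 18 were not called (adjusted p = 0.931 for the list with an estimated correlation), for example eif3l, a subunit of the initiation factor eIF3, at 79.1 ± 3.39 against 145 ± 25.2 TPM (-0.85 ± 0.12). The fatty acid elongase elovl5 was higher in the hybrid, at 364 ± 72.3 against 95.0 ± 8.10 TPM (1.91 ± 0.14).

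Of 37 lists, 4 were called against P. fulvidraco. The endoplasmic reticulum list had 0 higher and 18 lower of 28 measured members, 1 and 18 adjusted over the list alone (median -0.70, camera adjusted p = 1.21e-07, and adjusted p = 0.931 with an estimated correlation). Pdia6 differed by -1.11 ± 0.20, Dnajb9 by -0.94 ± 0.11 and HERPUD1, which acts in the degradation of misfolded proteins, by -0.72 ± 0.10. The translation list had 3 higher and 17 lower of 38 measured members, 6 and 22 adjusted over the list alone (median -0.40, camera adjusted p = 0.000466, and adjusted p = 0.931 with an estimated correlation). The initiation factor subunit EIF2S3 was at 63.5 ± 4.82 against 96.0 ± 8.97 TPM (-0.59 ± 0.10) and the cap-binding factor Eif4e at 1.41 ± 0.266 against 5.28 ± 1.88 TPM (-1.34 ± 0.24). The oxidative phosphorylation list had 3 higher and 14 lower of 66 measured members, 4 and 17 adjusted over the list alone (median -0.13, camera adjusted p = 0.00298, and adjusted p = 0.931 with an estimated correlation). NDUFA2 was at 106 ± 4.94 against 181 ± 11.4 TPM (-0.77 ± 0.08) and ndufa4 at 569.7 ± 25.7 against 814 ± 25.5 TPM (-0.51 ± 0.07). This call was lost under quantile normalization (camera adjusted p = 0.177) and with rows summed per symbol (0.0779), in a range of 0.000360 to 0.177 over the alternatives with the preset correlation. Pancreatic acinar markers had 2 higher and 0 lower of 12 measured members, 2 and 0 adjusted over the list alone (median 0.81, camera adjusted p = 0.0109, and adjusted p = 0.931 with an estimated correlation). Of the 2 members called, the row named Prss2 but described as a complement C1s subcomponent was listed at 0 in P. fulvidraco. The acinar list's call was lost without P. fulvidraco 1 (camera adjusted p = 0.118), without hybrid 1 (0.101) and without the pair of libraries rich in vitellogenin (0.313), in a range of 0.00118 to 0.313 over the alternatives with the preset correlation.

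**Figure D2:**
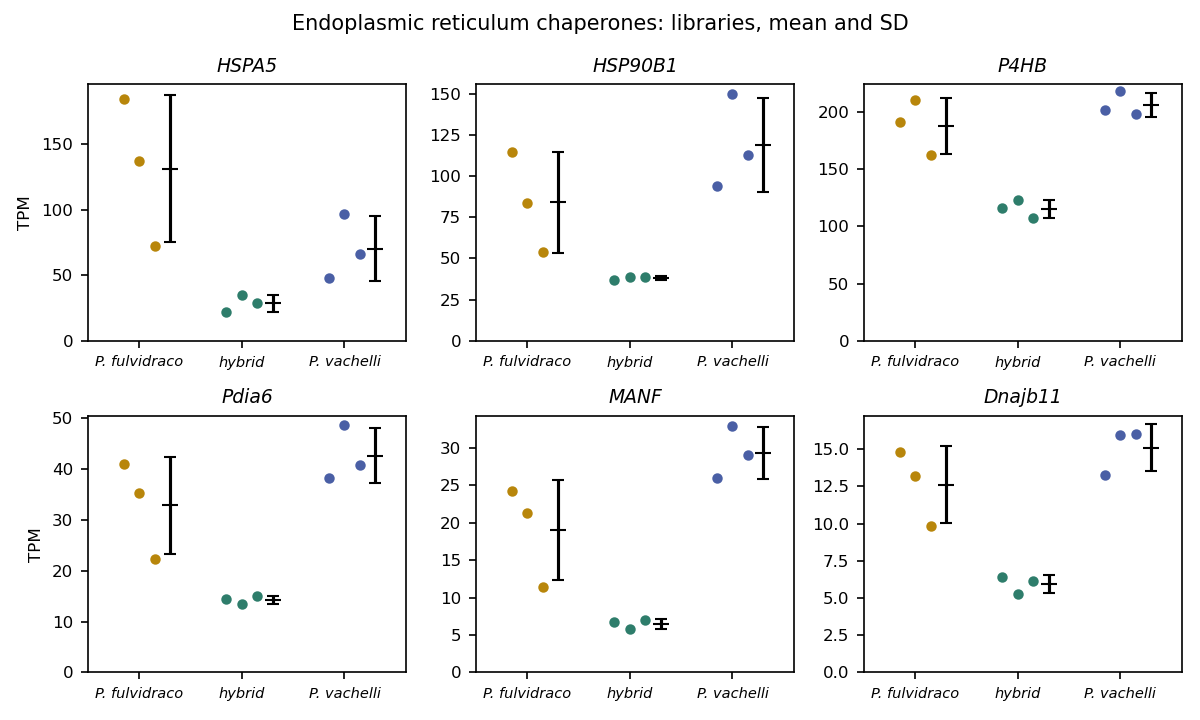
TPM of 6 endoplasmic reticulum genes in each library, with the mean and SD of the 3 libraries of each group. P4HB is at 115 ± 7.85 TPM in the hybrid, below the 188 ± 24.3 TPM of P. fulvidraco and the 206 ± 10.8 TPM of P. vachelli.

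The growth hormone and IGF list had 1 higher and 2 lower of 20 measured members, 1 and 2 adjusted over the list alone, and was not called (camera adjusted p = 0.867). The growth hormone receptor GHR was lower in the hybrid, at 42.5 ± 6.94 against 70.2 ± 6.44 TPM (-0.72 ± 0.15), beside 42.4 ± 7.17 TPM in P. vachelli. The binding protein IGFBP3 was at 4.72 ± 0.186 against 8.95 ± 0.989 TPM (-0.79 ± 0.15). Glycolysis and gluconeogenesis had 1 higher and 3 lower of 29 measured members, 4 and 5 adjusted over the list alone (median log2 difference 0.17, mean 0.12 and camera direction down). Pyruvate kinase pkm was at 208 ± 10.0 against 277 ± 18.7 TPM (-0.41 ± 0.08). Fatty acid and triglyceride synthesis had 5 higher and 2 lower of 21 measured members, 7 and 2 adjusted over the list alone. The acyl-CoA synthetase Acsl4 was at 20.2 ± 4.03 against 6.87 ± 2.27 TPM (1.45 ± 0.21) and dgat2, which makes triglyceride, at 88.2 ± 2.27 against 50.7 ± 7.16 TPM (0.79 ± 0.10).

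Further lists without a call against P. fulvidraco were those of dividing cells, lymphocytes, muscle and fat cells. The cell cycle list had 2 higher and 2 lower of 42 measured members, 1 and 1 adjusted over the list alone, with the mitotic checkpoint kinase Bub1b at 17.7 ± 4.10 against 1.38 ± 0.193 TPM (2.96 ± 0.18) and the replication nuclease fen1 at 4.31 ± 0.310 against 10.2 ± 1.94 TPM (-1.07 ± 0.15). Lymphocyte markers had 1 higher and 0 lower of 5 measured members, 1 and 0 adjusted over the list alone, the called member being CD22 (9.71 ± 2.86 against 3.29 ± 0.504 TPM, 1.29 ± 0.20). Skeletal muscle markers had 1 higher and 0 lower of 7 measured members, 1 and 0 adjusted over the list alone, with the calcium channel Ryr1 at 4.39 ± 1.62 against 0.0300 ± 0.0173 TPM (2.34 ± 0.49). Adipocyte markers had 0 higher and 2 lower of 6 measured members, 0 and 2 adjusted over the list alone. The vitellogenin gene vtg1, at 13377 ± 14295 TPM in P. fulvidraco, stood at 0.230 ± 0.234 TPM in the hybrid.

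Over all tested rows, 6095 were called higher and 5059 lower in the hybrid than in P. fulvidraco (limma, 21.8% of the rows), and 1144 and 1520 symbols after summing. Under quantile normalization 4809 rows were higher and 5385 lower. The total of 11154 rows fell to 6506 without P. fulvidraco 2. It was 2884 without both libraries rich in vitellogenin, where the single P. fulvidraco library left was assumed to vary like the other groups.

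The last comparison placed the hybrid against the mean of its parents, and asked which genes lay outside the parental range. Cysteine sulfinic acid decarboxylase, the enzyme of taurine synthesis, was above both parents in the rows Csad (415 ± 124 TPM, against 42.4 ± 14.7 and 56.9 ± 11.8 TPM) and GADL1 (123 ± 26.7 TPM, against 17.0 ± 4.60 and 16.3 ± 4.63 TPM). Of the row of intelectin itln, a lectin that binds microbial sugars, the hybrid held 676 ± 271 TPM, against 129 ± 18.8 and 5.97 ± 1.86 TPM. Summed over both rows of that symbol, the hybrid was not called above P. vachelli (903 ± 311 against 536 ± 100.4 TPM). Below both parents were members of the endoplasmic reticulum list and PRG4, the lubricant proteoglycan 4, at 3.42 ± 1.42 TPM against 20.9 ± 6.73 and 18.7 ± 8.65 TPM.

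**Figure D3:**
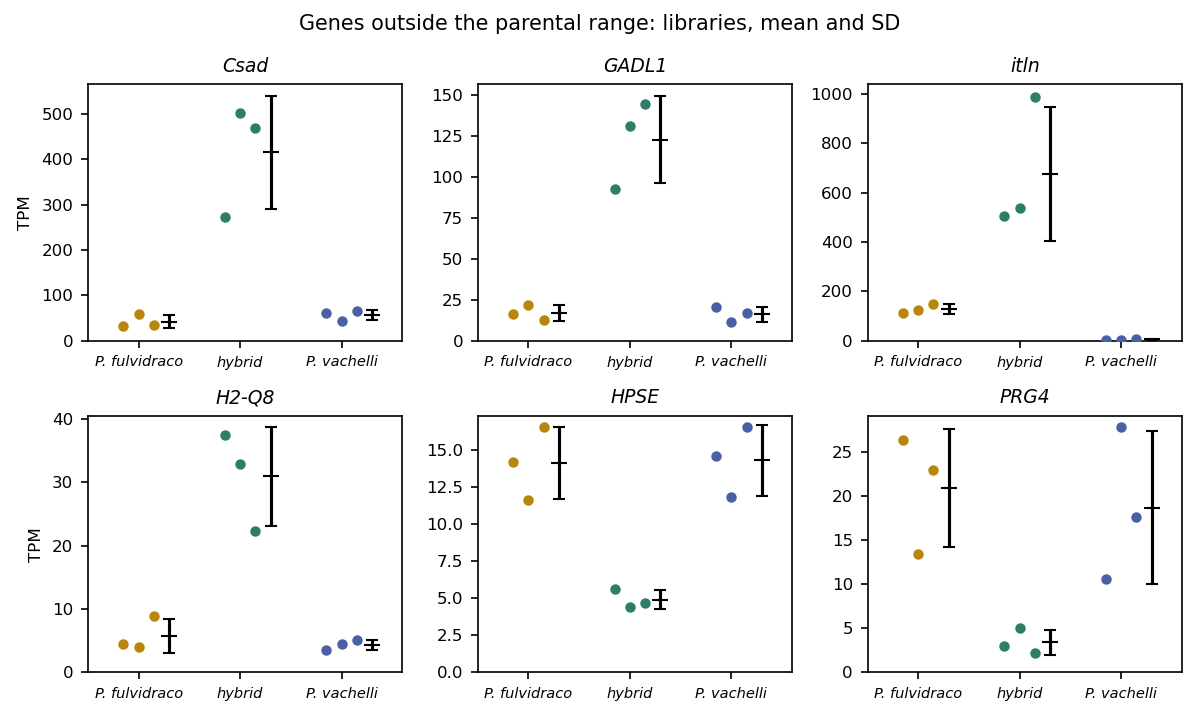
TPM of 6 genes outside the parental range in each library, with the mean and SD of the 3 libraries of each group. Csad is at 415 ± 124 TPM in the hybrid against 42.4 ± 14.7 and 56.9 ± 11.8 TPM in the parents, and HPSE at 4.91 ± 0.634 TPM against 14.2 ± 2.46 and 14.3 ± 2.38 TPM.

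Other rows above both parents were H2-Q7 and H2-Q8, described as MHC class I alpha chains, at 48.4 ± 33.9 and 30.9 ± 7.77 TPM. They stood at 4.36 ± 3.91 and 5.78 ± 2.68 TPM in P. fulvidraco and at 2.39 ± 1.51 and 4.38 ± 0.771 TPM in P. vachelli. From the fixed lists, the flavin monooxygenase Fmo5 differed from P. vachelli by 0.83 ± 0.12 and from P. fulvidraco by 1.11 ± 0.12, and serine dehydratase SDSL by 1.45 ± 0.17 and 0.97 ± 0.17. Heparanase HPSE was below both, with differences of -1.37 ± 0.17 from P. vachelli and -1.35 ± 0.17 from P. fulvidraco. In all, 442 rows were called above both parents and 326 below both (limma). Independent lists of the same sizes would overlap in 943 and 737 rows. In 20 simulations of unchanged groups that share the hybrid libraries, limma called at an adjusted p under 0.05 at most 0 rows (median 690.5 at an unadjusted p under 0.05). No row was changed in them, so the adjusted cut-off was stricter than in the data. The 0 is therefore no measure of the overlap that the shared libraries give here. Part of the overlap may come from the shared hybrid libraries, which are too few to split. Summed per symbol, 105 symbols were above and 217 below both parents.

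Of 37 lists, 10 were called against the mid-parent, the mean of both parents on the log scale. No list was tested against the mid-parent of the linear scale. The endoplasmic reticulum list had 0 higher and 17 lower of 28 measured members, 0 and 19 adjusted over the list alone (median log2 difference -0.50, camera adjusted p = 5.69e-13, and adjusted p = 0.771 with an estimated correlation). Of its 28 members, 11 were below both parents, against at most 2 in any other list. MANF differed from the mid-parent by -1.69 ± 0.21, Dnajb11 by -1.08 ± 0.14, P4HB by -0.76 ± 0.09 and creld2, a disulfide isomerase, by -1.54 ± 0.27. Pancreatic acinar markers had 5 higher and 0 lower of 12 measured members, 11 and 0 adjusted over the list alone (median 1.08, camera adjusted p = 2.32e-06, and adjusted p = 0.835 with an estimated correlation). These 12 include the row named Prss2 but described as a complement C1s subcomponent, no acinar product, whose level in the hybrid lay between the parents. The translation list had 0 higher and 6 lower of 38 measured members, 1 and 14 adjusted over the list alone (median -0.23, camera adjusted p = 1.29e-05, and adjusted p = 0.835 with an estimated correlation). The heat shock list had 1 higher and 4 lower of 21 measured members, 1 and 9 adjusted over the list alone (median -0.24, camera adjusted p = 0.0109, and adjusted p = 0.835 with an estimated correlation). That call was lost under quantile normalization (camera adjusted p = 0.0735), in a range of 0.000588 to 0.0735 over the alternatives with the preset correlation. The chaperone HSP90AA1 stood at 4.68 ± 1.52 TPM, against 10.8 ± 3.00 TPM in P. fulvidraco and 11 ± 3.52 TPM in P. vachelli.

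**Figure D4:**
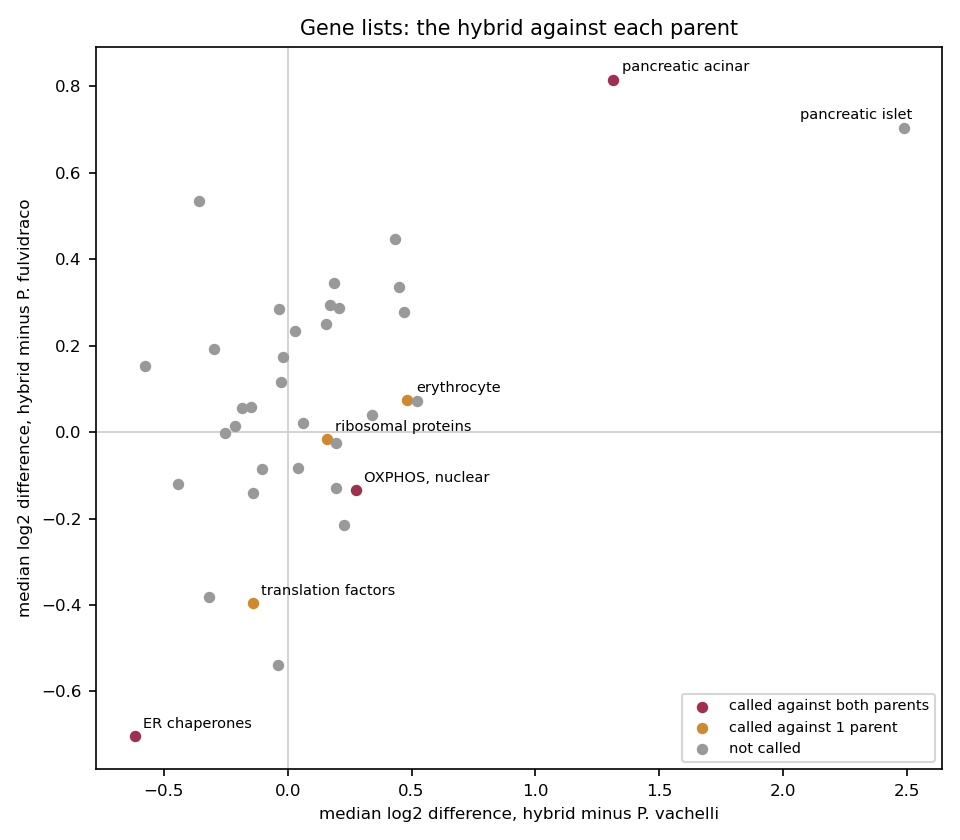
Median log2 difference of each of 37 lists between the hybrid and P. vachelli (horizontal axis) and between the hybrid and P. fulvidraco (vertical axis), each point a list. The endoplasmic reticulum list lies at -0.62 and -0.70, and the pancreatic acinar list at 1.31 and 0.81.

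Ribosomal proteins had 7 higher and 0 lower of 78 measured members, 9 and 0 adjusted over the list alone (median 0.12, camera adjusted p = 0.000678, and adjusted p = 0.835 with an estimated correlation). Their call was lost without hybrid 1 (camera adjusted p = 0.0608), in a range of 4.26e-08 to 0.0608 over the alternatives with the preset correlation. Fibroblast and stellate cell markers had 2 higher and 0 lower of 17 measured members, 6 and 0 adjusted over the list alone (median 0.37, camera adjusted p = 0.0109, and adjusted p = 0.835 with an estimated correlation), with collagen col1a2 at 58.9 ± 14.3 TPM against 34.1 ± 4.38 and 37.1 ± 7.03 TPM. Of the 9 fits without 1 library, limma called col1a2 only without hybrid 1 or P. vachelli 2 (adjusted p = 0.0556 to 0.130 in the other fits) and the other called collagen, COL6A3, only without hybrid 1 (adjusted p = 0.0579 to 0.120 in the rest). Nor did limma call COL6A3 with no filter (adjusted p = 0.0519) or with the replicate number as a block (0.0590). The list call was lost without hybrid 2 (camera adjusted p = 0.0530) and without hybrid 3 (0.192), in a range of 7.44e-06 to 0.192 over the alternatives with the preset correlation. The sterol and bile acid list had 1 higher and 0 lower of 30 measured members, 1 and 0 adjusted over the list alone (median 0.41, camera adjusted p = 0.0281, and adjusted p = 0.835 with an estimated correlation). Its called member Baat, which joins bile acids to amino acids, was at 469.7 ± 75.2 TPM, between the 32.8 ± 1.62 TPM of P. vachelli and the 739 ± 22.2 TPM of P. fulvidraco. The log-scale mid-parent can call an additive gene whose parents differ so widely. The sterol call was lost without P. fulvidraco 2 (camera adjusted p = 0.0835), without P. fulvidraco 3 (0.138), without hybrid 1 (0.220), without P. vachelli 1 (0.0845) and without P. vachelli 2 (0.0509), in a range of 4.9e-09 to 0.220 over the alternatives with the preset correlation.

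The remaining calls against the mid-parent were lost in several alternatives. Erythrocyte markers had 1 higher and 0 lower of 10 measured members, 1 and 0 adjusted over the list alone (median 0.31, camera adjusted p = 0.0248, and adjusted p = 0.835 with an estimated correlation). The erythrocyte call was lost with every row of a symbol as a member (camera adjusted p = 0.0785), without P. fulvidraco 1 (0.0596), without P. fulvidraco 2 (0.0560), without hybrid 1 (0.220), without P. vachelli 2 (0.0509), without P. vachelli 3 (0.0568) and without the pair of libraries rich in vitellogenin (0.200), in a range of 0.00375 to 0.220 over the alternatives with the preset correlation. Macrophage and Kupffer cell markers had 1 higher and 0 lower of 12 measured members, 1 and 0 adjusted over the list alone (median 0.29, camera adjusted p = 0.0440, and adjusted p = 0.835 with an estimated correlation). The called macrophage member, CD163, was at 501 ± 111 TPM in the hybrid against 836 ± 63.2 TPM in P. fulvidraco and 4.73 ± 1.46 TPM in P. vachelli. CD163 thus lay between its parents, and like Baat it may be called through the log scale of the mid-parent alone. The macrophage call was lost without P. fulvidraco 1 (camera adjusted p = 0.111), without P. fulvidraco 2 (0.0835), without hybrid 2 (0.175), without hybrid 3 (0.126), without P. vachelli 1 (0.0717), without P. vachelli 2 (0.0520), without P. vachelli 3 (0.0579) and without the pair of libraries rich in vitellogenin (0.389), in a range of 0.00267 to 0.389 over the alternatives with the preset correlation. The proteasome list had 0 higher and 2 lower of 39 measured members, 0 and 2 adjusted over the list alone (median -0.07, camera adjusted p = 0.0390, and adjusted p = 0.835 with an estimated correlation). Its called members psmd11b and PSME3 lost their limma calls in 7 and 6 of the 9 fits without 1 library (adjusted p up to 0.0756 and 0.0902), and without hybrid 1, hybrid 2, P. fulvidraco 2, P. vachelli 1 or P. vachelli 3 neither was called. With the replicate number as a block limma called neither (adjusted p = 0.0662 and 0.0676), and under median-ratio scaling it did not call psmd11b (0.0520). The proteasome call was lost under quantile normalization (camera adjusted p = 0.851), under median-ratio scaling (0.0737), with every row of a symbol as a member (0.0785), without P. fulvidraco 1 (0.0848), without P. fulvidraco 2 (0.0580), without hybrid 1 (0.188), without hybrid 2 (0.117), without P. vachelli 3 (0.0538), with rows summed per symbol (0.287) and without the pair of libraries rich in vitellogenin (0.321), in a range of 0.00963 to 0.851 over the alternatives with the preset correlation. The fasting and insulin response list was not called, with 1 higher and 3 lower of 24 measured members, 1 and 3 adjusted over the list alone. Its member CREB3L3, a liver factor of the fasting response, was at 13 ± 1.03 TPM against 17.3 ± 2.61 and 36.6 ± 3.13 TPM (-0.90 ± 0.11).

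Over all tested rows, 2888 were above and 1470 below the mid-parent of the log scale (limma). With the mid-parent taken on the linear scale, 982 were above and 2603 below, and under quantile normalization 3145 and 3312, so the direction of the excess depended on the scale. Under quantile normalization 408 rows were above and 512 below both parents, and without hybrid 3 348 and 402. The 4358 calls fell to 2733, 2854 and 2534 without P. vachelli 1, 2 or 3. The 768 rows outside the range fell to 487 without P. fulvidraco 2 and 471 without P. vachelli 3.

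Over the genes that differed between the parents, the hybrid lay between the parents in the median, nearer to P. fulvidraco. NDUFA2 stood at 106 ± 4.94 TPM, between 19.3 ± 1.21 and 181 ± 11.4 TPM and sod1 at 302 ± 33.8 TPM, between 113 ± 20.7 and 654 ± 33.0 TPM. On a scale with P. fulvidraco at 0 and P. vachelli at 1, the median position of the hybrid over the 27855 rows called between the parents was 0.442, and 0.426, 0.462 and 0.430 in the single libraries (SD 0.0197). Of those rows the hybrid was called different from P. vachelli alone in 9139, from P. fulvidraco alone in 5336, from both and between them in 4423, and from neither in 8772. All 3 libraries lay under the middle of 0.5, and a two-sided exact sign-flip test against it gave p = 0.25, the smallest that 3 libraries can give.

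Rows present in a single parent gave the share of that parent's level kept in the hybrid. 1454 rows reached 5 TPM in P. fulvidraco and stayed under 0.1 TPM in P. vachelli, and 1349 rows did the reverse. The hybrid held a median 43.5% ± 2.01 of the P. fulvidraco level and 33.6% ± 2.27 of the P. vachelli level (mean ± SD of 3 libraries). Of P. fulvidraco rows, that of complement component c3 stood at 1393 ± 383 TPM in P. fulvidraco and 543 ± 337 TPM in the hybrid, and a row described as apolipoprotein B-100, the main protein of very low density lipoprotein, at 1165 ± 45.7 and 593 ± 82.5 TPM. Of P. vachelli rows, that of complement factor I stood at 1218 ± 107 TPM in P. vachelli and 639.8 ± 80.7 TPM in the hybrid, and an inter-alpha-trypsin inhibitor heavy chain, a plasma protein, at 809 ± 125 and 426 ± 11 TPM.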

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

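Of the alternatives, the sums per symbol, the rows with both parents at 1 TPM or more, the rows with a protein description, the delta-method error and the fit without P. fulvidraco 1 and 2 were chosen after the results were seen. Quantile normalization, median-ratio scaling, no trend and no filter left every count of changed rows within 1.5 times its value in the report where they were run, and no called gene named in the text changed direction under the scalings, the filters, the replicate block or with a library left out. Quantile normalization moved the split to 3145 rows above and 3312 below the mid-parent (2888 and 1470 in the report) and to 408 above and 512 below both parents (442 and 326). A filter of 5 TPM, which tests fewer rows, gave 7735 rows for the hybrid against P. vachelli, 6506 against P. fulvidraco and 10618 between the parents. Against the mid-parent, a pseudocount of 0.1 gave 7074 rows (5478 above and 1596 below) and a pseudocount of 5 gave 2880, and the cause was not tested. With an absolute log2 difference of at least 1, fewer rows could pass: 10014 against P. vachelli, 6873 against P. fulvidraco, 2375 against the mid-parent and 357 outside the parental range. A fit of only the compared groups, with fewer libraries, gave 7402 rows against P. fulvidraco. Summed per symbol, with fewer rows tested, the counts were 3302 against P. vachelli, 2664 against P. fulvidraco, 5251 between the parents, 1169 against the mid-parent and 322 outside the range. In the same order they were 4914, 3826, 8692, 1417 and 384 in rows with both parents at 1 TPM or more, and 6095, 4607, 10101, 2130 and 477 in rows with a protein description. Without P. fulvidraco 1 and 2, with fewer samples, limma called 2884 rows against P. fulvidraco, 16960 between the parents, 2199 against the mid-parent and 267 outside the range. With 1 library of P. fulvidraco left, that library is assumed to vary like the other groups. The linear mid-parent with a delta-method error gave 839 rows above and 2163 below. The filter of 5 TPM gave 214 rows above and 357 below both parents, and the pseudocount of 0.1 269 and 375. The scaling moved the median of all rows by -0.09 at most, on the log2 scale, and quantile normalization gave 16 list calls up and 7 down, against 11 and 9 in the report. Besides those splits, the larger side of the rows higher and lower turned against P. vachelli (7928 and 7460 in the report) with quantile normalization (6312 and 8381), the pseudocount of 5 (6244 and 7675), the filter of 5 TPM (3862 and 3873), only the compared groups (6078 and 6715), sums per symbol (1477 and 1825), described rows (3001 and 3094), rows with both parents at 1 TPM or more (2156 and 2758), and without hybrid 3 (7081 and 7267). It turned against P. fulvidraco (6095 and 5059) with quantile normalization (4809 and 5385), the pseudocount of 5 (4440 and 5082), the filter of 5 TPM (3192 and 3314), sums per symbol (1144 and 1520), described rows (2284 and 2323) and rows with both parents at 1 TPM or more (1666 and 2160). Between the parents (14058 and 13797) it turned with the filter of 5 TPM (5143 and 5475), the pseudocount of 0.1 (13868 and 13871), sums per symbol (2585 and 2666), rows with both parents at 1 TPM or more (4294 and 4398), and without P. vachelli 1 (10450 and 11969), 2 (10484 and 11698) or 3 (10309 and 11832). Against the mid-parent it turned with sums per symbol (499 and 670) and rows with both parents at 1 TPM or more (657 and 760), and outside the range with sums per symbol (105 and 217), described rows (227 and 250), rows with both parents at 1 TPM or more (123 and 261), and without hybrid 3 (348 and 402). The split of list calls turned without P. vachelli 2 (7 and 10), P. vachelli 3 (6 and 8), hybrid 1 (6 and 8), P. fulvidraco 2 (8 and 9) or both P. fulvidraco 1 and 2 (9 and 12). Summing the rows of a symbol ended 2 list calls and added 9. With the correlation estimated per list, camera called 0 lists, and 1 test had an unadjusted p under 0.05. On rows summed per symbol, also with an estimated correlation and chosen after the results were seen, camera called 0 lists and 4 tests had an unadjusted p under 0.05. Leaving out single libraries gave 9043 to 15265 rows against P. vachelli, 6506 to 10527 against P. fulvidraco, 22141 to 27960 between the parents, 2534 to 3910 against the mid-parent, 471 to 750 outside the range, positions of 0.429 to 0.459 and 14 to 21 list calls. Counts moved by more than 1.5 times against P. vachelli without P. vachelli 1 (9320), 2 (9480) or 3 (9043), against P. fulvidraco without P. fulvidraco 2 (6506), against the mid-parent without P. vachelli 1 (2733), 2 (2854) or 3 (2534), and outside the range without P. fulvidraco 2 (487) or P. vachelli 3 (471). Of 1240 calls of named genes, 355 were lost without at least 1 library, 87 under quantile normalization, 64 under median-ratio scaling and 23 with no filter. The replicate numbers did not pair the samples, since residuals of libraries with the same number correlated by -0.112 to 0.0140 and 1 of 9 libraries correlated best with its own number. The replicate block gave 14006, 9430, 27204, 3138 and 622 rows in the same order, a position of 0.439 and 20 list calls, and 140 of the calls of named genes were lost under it. A split of the hybrid libraries shared by both parental comparisons was not possible with 3 of them, and the unknown depth leaves open how precise single values are.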

Other observations

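Chosen only after the result was seen were the tests that weigh explanations of the endoplasmic reticulum pattern and the restriction to rows with both parents at 1 TPM or more. Several liver genes differed between the hybrid and P. vachelli while their levels in the hybrid lay near those of P. fulvidraco. The glutathione transferase GSTO1 stood at 26.4 ± 1.90 TPM in the hybrid, 30.8 ± 3.68 TPM in P. fulvidraco and 9.56 ± 0.922 TPM in P. vachelli (log2 difference from P. vachelli 1.37 ± 0.12), and GSTP1 of the same enzyme family at 292 ± 21.4, 295 ± 60.4 and 90.5 ± 5.02 TPM (1.68 ± 0.15). The cytochrome P450 gene CYP2J2 stood at 1036 ± 96.4, 1034 ± 94.0 and 324 ± 28.0 TPM (1.68 ± 0.11). The complement gene C7, part of the membrane attack complex, stood at 114 ± 6.12, 121 ± 23.6 and 375 ± 72.5 TPM (-1.70 ± 0.17). The tryptophan-degrading enzyme IDO2 was higher in the hybrid than in P. vachelli, at 40.4 ± 6.62 against 6.72 ± 2.22 TPM (2.45 ± 0.22). Among genes that lay between the parents, Decr1, an enzyme of unsaturated fatty acid oxidation, stood at 14.6 ± 0.929 TPM, with 7.90 ± 0.641 TPM in P. fulvidraco and 28.9 ± 1.42 TPM in P. vachelli (0.81 ± 0.10 from P. fulvidraco and -0.94 ± 0.10 from P. vachelli), and the small heat shock protein gene HSPB8 at 5.01 ± 0.288, 0.297 ± 0.131 and 10.0 ± 0.899 TPM (2.22 ± 0.15 and -0.88 ± 0.15). Apolipoprotein APOA4 was lower in the hybrid than in P. fulvidraco, at 506 ± 122 against 1719.7 ± 339 TPM (-1.77 ± 0.20).

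22 rows, chosen after their values were seen, had a human protein as their best match, and 14 of these were at 0 in P. fulvidraco 1, P. vachelli 2 and P. vachelli 3 and above 0 in all hybrid libraries and P. fulvidraco 3. 118 tested rows share that profile, 16 of them above both parents, and together they held 329, 311 and 565 TPM in hybrid 1, 2 and 3 and 354 TPM in P. fulvidraco 3, beside 183 TPM in P. fulvidraco 2 and 94.7 TPM in P. vachelli 1.

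The endoplasmic reticulum chaperone list was lower in the hybrid than in both parents, with adjusted p of 0.000151 to 0.0111 against P. vachelli and 9.59e-11 to 6.96e-05 against P. fulvidraco over the alternatives other than the estimated correlation, with which the call was lost (adjusted p = 0.774 and 0.931). A division of hybrid reads between parental rows of the same symbol is argued against for the members called. With rows summed per symbol, limma called 17 and 16 of 28 members lower against the 2 parents. The larger camera adjusted p of the list was then 0.000275, but adjusted p = 0.705 and 0.947 with an estimated correlation. Rows without a symbol or with another symbol were not in these sums, so a division with such rows stays open. Fewer pancreatic acinar cells, which are rich in these chaperones, would lower the acinar list as well, and its median log2 difference from the mid-parent was 1.08. Vitellogenin synthesis in P. fulvidraco stays open for the comparison with P. fulvidraco: without P. fulvidraco 1 and 2 the list was still lower (camera adjusted p = 2.56e-05), but on 1 P. fulvidraco library. A difference in feeding or sampling could also lower these genes and stays open, like the hybrid genotype itself, since line and aquaria cannot be told apart. The fasting list was not called against the mid-parent (camera adjusted p = 0.159). It was called in 1 of the 15 alternatives with the preset correlation (range 0.0351 to 0.454).

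More rows lay above than below the mid-parent on the log scale (66.3% of the calls). The mean of the parents taken on the log scale may produce this excess, since on the linear scale rows above made up 27.4%. Rows found in 1 parent only may add to it, since rows above made up 46.4% where both parents had at least 1 TPM. No biological explanation was tested for the excess.

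The hybrid kept more of the level of P. fulvidraco rows than of P. vachelli rows, with gaps of 12.8, 5.05 and 11.9 percentage points in hybrid 1, 2 and 3. Drop-out of rows of low level is argued against, since among rows of at least 20 TPM the smallest gap was 6.29 points. With vitellogenin rows removed the smallest gap was 4.09 points, under the bound of 5 set before, so vitellogenin may contribute, but that gap was 5.05 before removal and all 3 gaps stayed above 0 (11.6 and 11.2 in the others). An assembly or quantification that favours P. fulvidraco sequence stays open without reads or sequences: in 6 symbols with rows of each parent the mean gap was 40.9 ± 9.31 points (SD of 3 libraries), and 29.0 ± 14.8 points without MT-ND2, a mitochondrial gene inherited from the mother. A biological preference for maternal alleles was not tested.

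Other splits of the libraries were refitted. Of the 10 splits of 6 libraries only 1, the real one, reached its count in each pair of groups, and 10 splits are too few for a share under 0.05: the real counts were 15388, 11154 and 27855 rows and the highest others 0, 476 and 0, for the hybrid with P. vachelli, the hybrid with P. fulvidraco and the parents. At an unadjusted p under 0.05, limma gave 2175, 3350 and 1014 rows in the highest other splits and 21407, 18136 and 30780 in the real ones. Of 100 splits of the 9 libraries, the real one included and the others drawn, 3 reached the 4358 rows called against the mid-parent (highest other 12647). The 768 rows outside the range were reached in 3 (highest other 4777) and the 10 list calls against the mid-parent in 2 (highest other 10), the real one again included. Most other splits also gave list calls, even where limma called 0 rows against the mid-parent. Camera called 10 lists and limma 0 rows in a split with P. fulvidraco 1, P. vachelli 1 and P. vachelli 3 in the place of the hybrid. With hybrid 1, P. fulvidraco 1 and P. vachelli 3 there, a split gave 9 lists and 0 rows. List calls at the preset correlation thus did not need the real groups. Nearly all of the other splits mix the lines, whose differences then enter the residual spread, so no exclusion of chance is drawn from these shares. The splits with several times the real counts of rows set the 3 P. fulvidraco libraries together in the place of the hybrid, which points to the structure of the 3 lines.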
